A study of Rattus norvegicus with 3 samples.

How the data were processed

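The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of enamel organ, the epithelial tissue that forms tooth enamel, dissected from the continuously growing lower incisors of adult wild-type rats. It has 3 libraries: an input without antibody, a ChIP of DLX3, a homeodomain transcription factor, and a ChIP of H3K4me3, the trimethylation of histone H3 at lysine 4 that marks active promoters. There is 1 library per antibody, so no value has a replicate and no spread between animals can be given. Peak lists of the 2 ChIP libraries were analysed, and no value was computed directly from the input library. Per the labels' protocols, tissue was fixed with formaldehyde and sonicated, and adapter-ligated DNA was amplified by PCR, selected by size on a gel and sequenced on Illumina HiSeq instruments.

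The titles and the series' design name DLX3 and H3K4me3, whereas the antibody field of the same samples reads anti-DLX4 and anti-H3K4me4. Groups were taken from the titles. The peak lists contain nothing that could tell DLX3 from its relative DLX4, and lysine tetramethylation is not a known histone mark.

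Per the submitters' processing notes, Bowtie 1.1.2, MACS 1.4.2 and HOMER were used with the rat genome build rn5. The notes as available here give no roles, mapping filters or cutoffs. The peak names in both lists are those MACS writes, 1 list was deposited per ChIP library, and the numbers in the peak names run from 1 to the last peak without a gap, so no peak is missing from within either numbering. Each list gives a chromosome, a start, an end and a score per peak. The score is the authors' deposited value; in this version of MACS it is by convention a scaled negative log10 of the p-value, which no file header states. Scores began at 50.0 in the DLX3 list and 50.01 in the H3K4me3 list. A score of exactly 3100 was shared by 7 DLX3 and 2454 H3K4me3 peaks, so the score ranks the strongest peaks of both lists poorly. The shared value may be a ceiling set in peak calling. Whether scores above 3100 mark stronger peaks than 3100 itself is not known. Scores were compared only within a list: to rank or split its peaks, and as medians or quartiles of classes of its peaks or of chromosomes. The lists hold no read counts, so the depth is unknown, and the number of peaks called in a library depends on it. Whether the input served as the control of the peak calling is not given in the sources used here. If it did not, regions that are recovered well from any chromatin, such as open promoters, could be called in both lists.

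Positions are given as in the deposited lists, in rn5, with starts counted from 1. The gene table in hand is of another build, GRCr8, and its coordinates cannot be joined to rn5 positions. The planned comparisons that need an rn5 annotation or sequence (peaks at annotated promoters, 16 fixed lists of genes and cell type markers, the homeobox motif and other motifs) were therefore not analysed here, and regions are named by position, without genes.

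Overlap between the lists was counted as at least 1 bp shared, with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The counts equal those of bedtools 2.31.1. Shares carry 95% Wilson intervals, which cover counting error only: neighbouring peaks are not independent, and peaks are not replicates. Overlap was set beside 1000 random placements of the DLX3 peaks, each kept at its width and on its chromosome, whose length was taken as the largest peak end in either list; distances, score deciles, clustering and the alternatives used 200 placements or fewer. Placements describe these libraries and give no p-value for the tissue. Differences between median scores carry bootstrap intervals from 1000 draws of peaks. On simulated lists of 69263 peaks, shares set at 10% and 50% were recovered as 10.002% and 50.002%, and randomly placed peaks gave a fold over random placement of 0.976. These simulations check the counting only. They do not show that random placement is a fair comparison for clustered peaks.

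Before the data were examined, the positions to name were fixed: the 10 DLX3 and 5 H3K4me3 peaks of highest score, the 5 widest H3K4me3 peaks and the 5 windows of 100 kb with the most DLX3 peak centres, with ties ordered by chromosome and start. Other thresholds of score, overlap, width and window were also fixed then. Joining of peaks within 200 bp for the overlap and the clustering, and within 1 kb for the clustering, the 200 bp DLX3 peaks against full H3K4me3 peaks, the local and gap-free placements, the shifted windows, the distance classes, the place of DLX3 peaks within H3K4me3 peaks, and the limit of 10 peaks for a dense window were chosen after seeing the data.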

Results

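DLX3 occupancy and H3K4me3 were profiled by ChIP-seq in the enamel organ of adult rat incisors, with 1 library each, to locate the binding sites of DLX3 in this tissue. The antibody field of the labels names DLX4 and H3K4me4 instead, and the titles were followed. The DLX3 list held 69263 peaks and the H3K4me3 list 25094, on chromosomes 1 to 20 and X, a ratio of 2.76. DLX3 peaks were narrower, with a median width of 999 bp (quartiles 710 and 1476 bp) against 1757 bp (quartiles 1183 and 2556 bp) for H3K4me3. Together the DLX3 peaks covered 85.8 Mb, or 2.96% of the span of the chromosomes, and the H3K4me3 peaks covered 51.6 Mb, or 1.78%. The median peak score was 92.3 in the DLX3 list (quartiles 64.5 and 160.0) and 451.2 in the H3K4me3 list (quartiles 94.6 and 1872). Scores of the lists are not on a common scale, because the depth of the libraries is unknown.

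The first question was how far DLX3 sites coincide with promoters carrying the active mark. Of the DLX3 peaks, 17577 (25.4%, Wilson interval 25.1 to 25.7%) overlapped an H3K4me3 peak by at least 1 bp, and 51686 (74.6%) lay outside the mark. Seen from the other list, 16031 of the H3K4me3 peaks (63.9%, Wilson interval 63.3 to 64.5%) contained or touched a DLX3 peak, and 9063 did not. The gap between these shares follows largely from the lengths of the lists, since most overlaps pair 1 peak with 1 peak. With only the 25094 highest-scoring DLX3 peaks, the shares were 40.2% and 38.4%, which equal lengths bring close by construction. Most marked regions with DLX3 held a single DLX3 peak: 14506 H3K4me3 peaks had 1, 1359 had 2, and 166 had 3 or more. Random placement of the DLX3 peaks gave an overlap of 3.15% ± 0.066 (SD over 1000 placements) and at most 3.34%, so the observed share was 8.06 times the random one. For the H3K4me3 peaks the random share was 8.44% ± 0.174 (SD over 1000 placements), and the observed share was 7.57 times that. When each DLX3 peak was instead moved by up to 100 kb from its own place, the overlap was 8.28%, and the observed share was 3.07 times this local value. With 1 library per antibody there is no replicate check on either share.

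The overlap was most frequent among the strongest peaks of both lists. In the lowest score decile of DLX3 peaks, 11.1% overlapped H3K4me3 (Wilson interval 10.4 to 11.8%), and in the highest decile 53.2% did (52.1 to 54.4%). Random placement gave 2.71% and 4.13% for these same deciles, so the fold over random placement was 4.08 in the lowest and 12.9 in the highest. The median score of DLX3 peaks on the mark was 140.5 (quartiles 84.1 and 253.3) against 83.1 (quartiles 61.7 and 132.6) off the mark, a difference of 57.4 (bootstrap interval 55.3 to 60.0 over peaks). DLX3 peaks on the mark were also wider, with a median of 1448 bp against 888 bp. Within each of 4 equal classes of peak width the score difference kept its sign but was smaller, from 7.68 in the narrowest class to 48.3 in the widest. Among H3K4me3 peaks, the share with DLX3 lay between 44.3% and 47.8% in each of the 5 lowest score deciles, then increased through 57.2%, 73.7%, 84.1% and 92.4% to 97.3% in the highest decile (Wilson interval 96.6 to 97.9%). Of the 2730 H3K4me3 peaks with a score of 3100 or more, 2660 overlapped DLX3 and 70 did not. Stronger H3K4me3 peaks were also wider, and the random share increased from 5.98% in the lowest decile to 12.2% in the highest. The fold over random placement was 7.41 in the lowest H3K4me3 decile, 6.25 in decile 5, 8.80 in decile 9 and 7.94 in the highest. In the upper deciles a share near 100% cannot give a much higher fold, so these folds are not comparable with those of the DLX3 deciles.

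**Figure D1:**
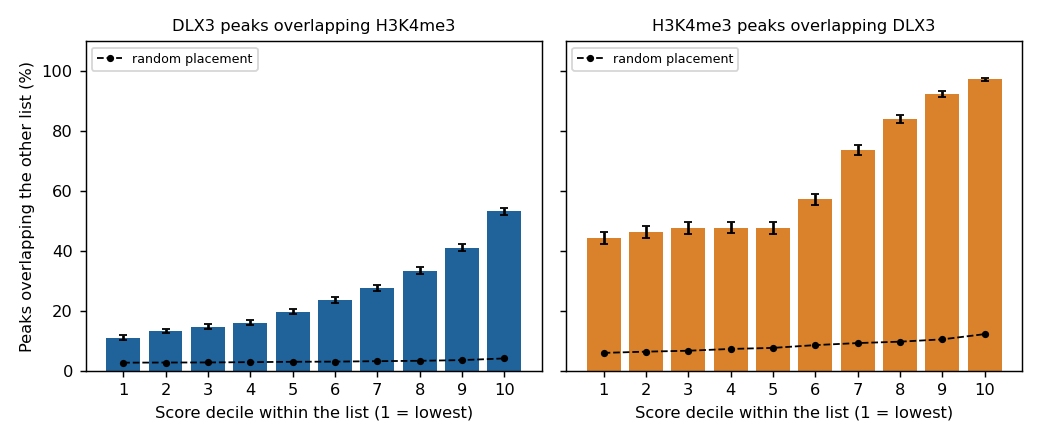
Share of peaks overlapping the other list (y axis, %) by score decile within the list (x axis), for DLX3 peaks (left) and H3K4me3 peaks (right); bars are observed shares with 95% Wilson intervals, and black points the means of 200 random placements. The DLX3 share increased from 11.1% to 53.2%, and the H3K4me3 share stayed near 44.3% to 47.8% over the lower deciles before it increased to 97.3%.

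DLX3 peaks outside the mark lay nearer to it than random placement over the whole chromosome gave. Distances were not set beside peaks moved locally, so regions dense in both lists may account for this nearness. Of the DLX3 peaks, 1875 (2.71%) did not overlap but lay within 1000 bp of the nearest H3K4me3 peak, 13225 (19.1%) lay beyond that and up to 10000 bp away, and 31318 (45.2%) lay farther off, up to 100000 bp away. Random placement gave 1.68%, 11.7% and 37.2% for these classes, so the folds over random placement were 1.61, 1.63 and 1.22. The median distance of the peaks outside the mark was 21212 bp. Distances over 100000 bp were found for 5268 peaks (7.61%, Wilson interval 7.41 to 7.81%), against 46.3% ± 0.191 (SD over 200 placements) of randomly placed peaks, a fold of 0.164. Peaks in these 4 distance classes had similar median scores, 86.8, 84.9, 82.7 and 79.2 from the nearest to the farthest class, all below the 140.5 of peaks on the mark.

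**Figure D2:**
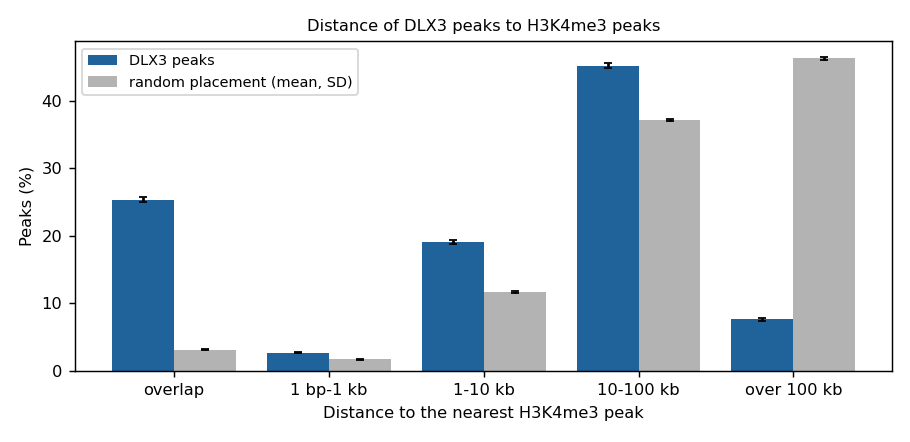
Share of peaks (y axis, %) by distance to the nearest H3K4me3 peak (x axis), for the observed DLX3 peaks (blue, 95% Wilson intervals) and for random placements (grey, mean and SD over 200). Of the DLX3 peaks 25.4% overlapped the mark and 7.61% lay over 100 kb away, against 46.3% over 100 kb for random placement.

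Within marked regions, the midpoints of DLX3 peaks lay near the middle of the H3K4me3 peak. Of 16871 DLX3 peak centres inside an H3K4me3 peak, 14240 (84.4%, Wilson interval 83.9 to 84.9%) fell in the central 50% of its length, where an even spread would put 50%. Of 10 equal bins of the distance from centre to edge, the innermost held 27.9% of the centres and the outermost 0.942%. The lists give peak edges and not summits, so the centre is the midpoint of the called region. The even spread takes no account of width. DLX3 peaks on the mark had a median width of 1448 bp, and H3K4me3 peaks with DLX3 had 2089 bp. A DLX3 peak lying inside a marked region not much wider than itself has its midpoint near the middle. No comparison matched on width was run, so central binding of DLX3 is not shown.

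**Figure D3:**
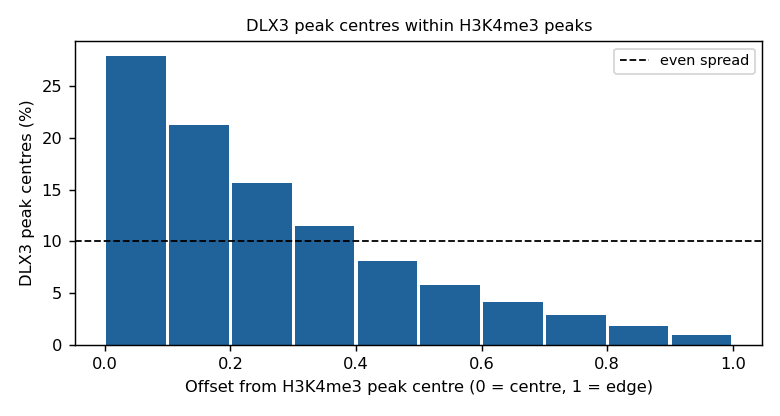
Share of DLX3 peak centres inside an H3K4me3 peak (y axis, %) by offset from the centre of that peak, as a fraction of the distance to its edge (x axis); the dashed line marks an even spread. The innermost bin held 27.9% of centres and the outermost 0.942%. The even spread takes no account of the width of the DLX3 peaks.

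The DLX3 sites of highest score were wide regions, and most of them carried the promoter mark. Of the 10 DLX3 peaks with the highest score, 8 overlapped an H3K4me3 peak. The highest score, 3218, belonged to a peak of 9921 bp on chromosome 2 (223438568 to 223448488), which lay outside the mark, 10235 bp from the nearest H3K4me3 peak. The next, with a score of 3191, was 12318 bp wide on chromosome 16 (70918524 to 70930841) and lay 16489 bp from the nearest H3K4me3 peak. The third, with a score of 3131, spanned 7751 bp on chromosome 6 (115988190 to 115995940) and overlapped an H3K4me3 peak with a score of 3100. The other 7 shared the score of 3100, which may be a ceiling, so they need not be weaker than the peaks named before them. They were on chromosome 1 (86590440 to 86600342), chromosome 5 (117956650 to 117962926), chromosome 10 (86749181 to 86763718 and 87909969 to 87918178), chromosome 11 (36142252 to 36152641), chromosome 19 (37067147 to 37070889) and chromosome 20 (39615956 to 39623832). The H3K4me3 peak under the chromosome 11 site had a score of 326.2, and those under the other 6 had 3100.

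The 5 H3K4me3 peaks named for the highest score shared the value 3233, which need not mean a stronger signal than the common score of 3100. Those on chromosome 3 (163094158 to 163095942) and chromosome 9 (37460689 to 37463281) overlapped no DLX3 peak, and the nearest were 144 bp and 4275 bp away. Those on chromosome 10 (62795599 to 62797523), chromosome 11 (90432563 to 90434223) and chromosome 19 (738297 to 740724) each overlapped 1 DLX3 peak, with scores of 92.8, 286.7 and 196.3. These 5 do not stand for all strong peaks, since 97.4% of those with a score of 3100 or more overlapped DLX3. The 5 widest H3K4me3 peaks all held DLX3 peaks. Adjoining peaks of 22306 bp and 19135 bp on chromosome 7 (12564889 to 12587194 and 12587290 to 12606424) held 2 and 3. Peaks of 18817 bp on chromosome 10 (109007182 to 109025998) and 18199 bp on chromosome 19 (63745290 to 63763488) held 6 each, and 1 of 17584 bp on chromosome 18 (70525656 to 70543239) held 4, the highest with a score of 2023.

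DLX3 peaks were gathered in clusters along the chromosomes. Of the 29016 windows of 100 kb, 14289 held at least 1 DLX3 peak and 1923 (6.63%) held 10 or more. These dense windows contained 27675 DLX3 peaks, 40.0% of the list (Wilson interval 39.6 to 40.3%), against 0.604% ± 0.0827 (SD over 200 placements) of randomly placed peaks. Random placement takes no account of gene density, and the same measure was not run on the H3K4me3 list. The excess is therefore not shown to be particular to DLX3. Some other settings gave lower shares at the same limit of 10, and other limits were not run. The share was 17.3% for the upper 50% of DLX3 peaks by score and 14.7% with windows of 50 kb. It was 22.0% of regions after joining DLX3 peaks within 1 kb. Random shares under these settings were 0.00693%, 0.00612% and 0.142%. The fullest window held 43 DLX3 peaks, and the fullest window of any random placement held 17. Dense windows had a median of 3 H3K4me3 peaks, and 206 of them (10.7%) had none. Over all 29016 windows there were 25094 H3K4me3 peaks, fewer than 1 per window, so dense windows were mostly rich in the mark.

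The 5 densest windows differed in their promoter mark. The window on chromosome 14 (59300001 to 59400000) held 43 DLX3 peaks and 1 H3K4me3 peak, with a median DLX3 score of 91.9. On chromosome 9, the window from 17500001 to 17600000 held 42 DLX3 peaks with a median score of 223.6 and a highest of 1993, and 5 H3K4me3 peaks; 7 of its DLX3 peaks overlapped the mark, and DLX3 peaks covered 77.1 kb of sequence. A second window on chromosome 9 (63300001 to 63400000) held 41 DLX3 peaks and 1 H3K4me3 peak. The window on chromosome 4 (6700001 to 6800000) held 39 and 3. The window on chromosome 16 (50100001 to 50200000) held 38 DLX3 peaks, with a highest score of 1120, and no H3K4me3 peak. Some of these peaks adjoin: joining DLX3 peaks within 200 bp left 32, 22, 35, 23 and 31 separate regions in the 5 windows, in the order given.

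**Figure D4:**
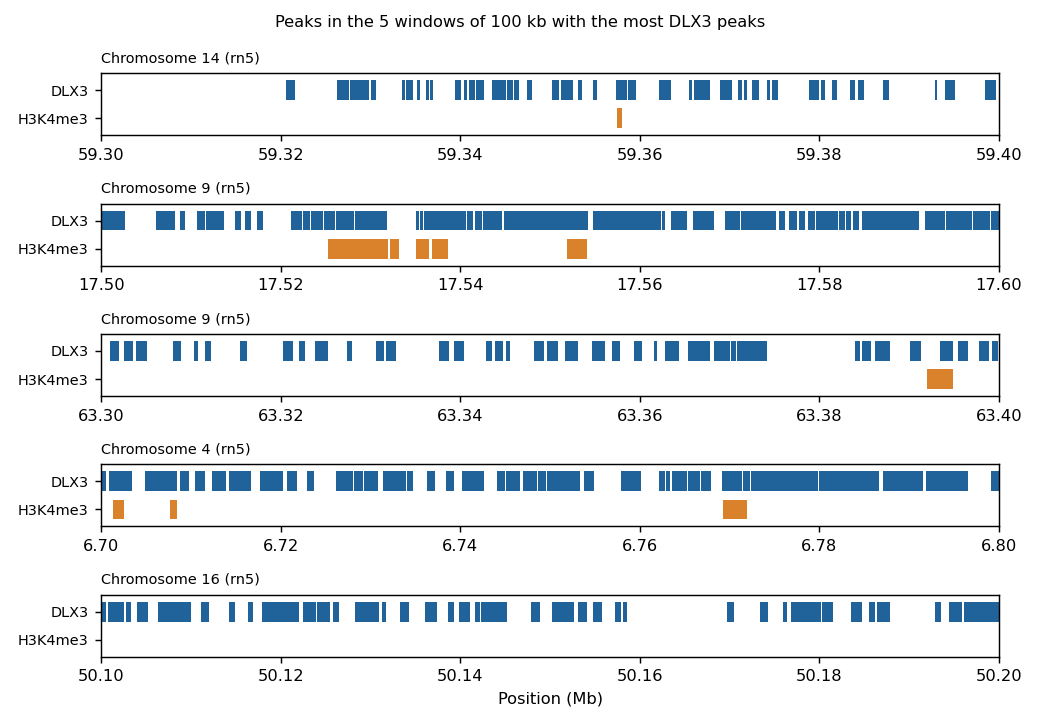
Maps of the 5 windows of 100 kb with the most DLX3 peaks, with rn5 position in Mb on the x axis; blue blocks are DLX3 peaks and orange blocks H3K4me3 peaks, drawn to scale and clipped at the window edge. The windows hold 38 to 43 DLX3 peaks and 0 to 5 H3K4me3 peaks.

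The chromosomes differed in the density of both lists, and X stood apart for DLX3. Chromosome 12 had 45.8 DLX3 peaks per Mb and chromosome 10 had 44.8, and these chromosomes were also the densest in H3K4me3, with 15.8 and 18.0 peaks per Mb. Among the 20 autosomes the lowest DLX3 density was 16.1 peaks per Mb, on chromosome 2. The lengths used include stretches without any peak, up to 65.5 Mb on chromosome 4, which lower the densities of the chromosomes that hold them. Chromosome X had 716 DLX3 peaks, or 4.63 per Mb against 24.96 over the autosomes, a density ratio of 0.186 (95% counting interval 0.172 to 0.200). Its H3K4me3 density was 3.99 per Mb against 8.91, a ratio of 0.447 (0.413 to 0.484). There were 1.16 DLX3 peaks for each H3K4me3 peak on X, and 2.42 to 3.32 on the autosomes. The shortfall was greater off the mark: DLX3 peaks without H3K4me3 had a density ratio of X to autosomes of 0.128 (0.115 to 0.142), and those with H3K4me3 0.358 (0.322 to 0.398). Accordingly 48.5% of the DLX3 peaks on X overlapped H3K4me3 (Wilson interval 44.8 to 52.1%), against 20.9 to 30.1% on the autosomes. Of the H3K4me3 peaks on X, 52.8% had DLX3 (48.8 to 56.7%), against 61.8 to 67.3%. The median DLX3 score on X, 97.8, was not lower than on the autosomes. The medians are not like for like, since more of the X peaks lay on the mark, where scores were higher. The sex of the animals is not among the labels used here.

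**Figure D5:**
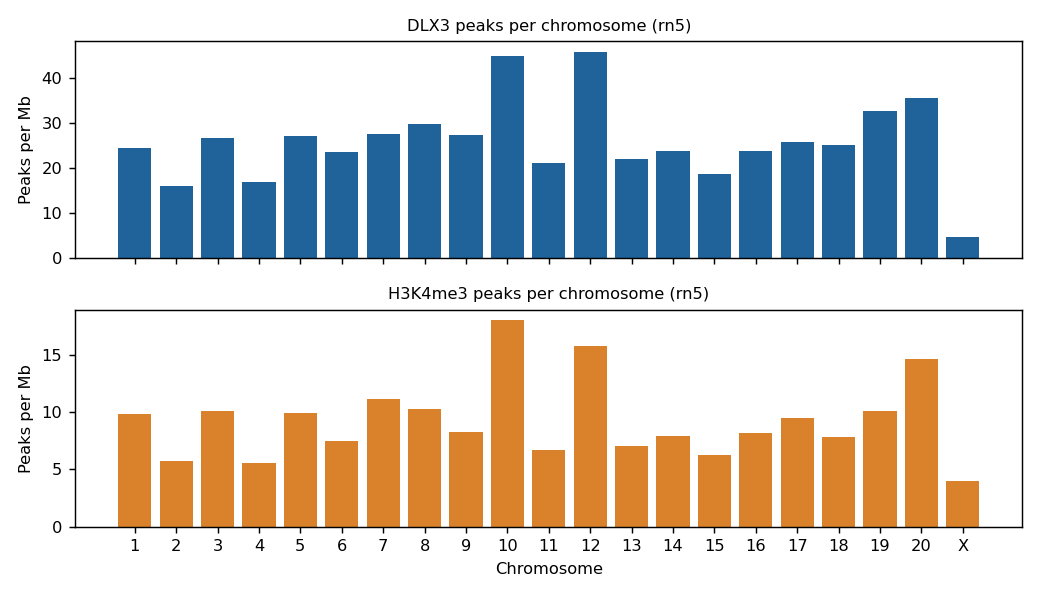
Peaks per Mb (y axes, starting at 0) on each chromosome (x axis) in the DLX3 list (top) and the H3K4me3 list (bottom), with chromosome length taken as the largest peak end. Chromosome X has 4.63 DLX3 and 3.99 H3K4me3 peaks per Mb, the lowest value of each list.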

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

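The overlap of DLX3 with H3K4me3 exceeded random placement under each of the 10 alternatives run, by 5.82 to 31.2 times for the DLX3 share and by 5.20 to 31.4 times for the H3K4me3 share, but the shares themselves moved. The DLX3 share was 35.8% for the upper 50% of DLX3 peaks by score, 16.6% against the upper 50% of H3K4me3 peaks, and 40.2% with both lists at the length of the shorter one; the H3K4me3 share was 46.8%, 81.0% and 38.4% under these settings. With at least 50% of the DLX3 peak covered the shares were 24.1% and 61.2%, with the DLX3 centre inside the H3K4me3 peak 24.4% and 61.8%, and with peaks within 1 kb counted 28.1% and 68.2%. Reducing every peak to 200 bp gave 11.99% and 33.1%, and reducing only the DLX3 peaks gave 24.6% and 62.3%. Joining peaks within 200 bp gave an H3K4me3 share of 65.0%. The fold over random placement was 7.67 with empty stretches over 5 Mb left out, and 3.07 with peaks moved by up to 100 kb. The higher score of DLX3 peaks on the mark was 7.68, 14.7, 30.3 and 48.3 in the 4 classes of width from narrow to wide, and 49.98 in the upper 50% by score, so part of the difference of 57.4 goes with width. The share of DLX3 peaks in dense windows was 14.7% with windows of 50 kb, 17.3% for the upper 50% by score, 34.1% of regions after joining peaks within 200 bp and 22.0% after joining those within 1 kb, where the same limit of 10 peaks is harder to reach. The ratio of DLX3 density on X to that on the autosomes was 0.205 with empty stretches left out of the spans. Taking the upper 50% by score left 34631 DLX3 peaks over 54.2 Mb and 12547 H3K4me3 peaks, by construction. The cause of the other movements was not tested. Planned comparisons with rn5 promoters, gene lists and motifs, with their alternatives, were not run. No paired analysis was possible because there is 1 library per antibody, and no library could be left out in turn. Depth is unknown, so a site outside the lists may have lacked reads.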

Other observations

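The tests in this part were chosen after the results they address had been seen. Dense windows of DLX3 peaks without any H3K4me3 peak hold many DLX3 sites away from the promoter mark. After the chromosome 16 window already described, the fullest of the 206 were on chromosome 1 (207600001 to 207700000, 33 DLX3 peaks, and 130000001 to 130100000, 32 peaks), chromosome 2 (219700001 to 219800000, 31 peaks) and chromosome 9 (46400001 to 46500000, 31 peaks). The nearest H3K4me3 peak lay 24.4, 9.19, 4.22 and 46.2 kb outside these windows. The highest DLX3 scores in them were 691.6, 603.5, 336.3 and 502.0.

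Wide H3K4me3 peaks held more DLX3 peaks. In the widest decile, 3555 to 22306 bp, 92.3% overlapped DLX3 (Wilson interval 91.2 to 93.2%) and 33.0% held 2 or more DLX3 peaks. In the narrowest decile, 280 to 844 bp, these shares were 25.9% (24.2 to 27.6%) and 0.159%. A wider peak also has more room for overlap.

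Overlap of DLX3 with the promoter mark was above random placement. Width of the DLX3 peaks was matched already, since each placement kept the widths. With every DLX3 peak reduced to 200 bp, 24.6% overlapped, no placement gave over 2.35%, and the fold was 11.2. A high fold at that width is therefore no separate test of width. Large regions dense in both lists as the whole cause are argued against by the fold of 3.07 that remained after moving each DLX3 peak by up to 100 kb, where no moved set gave over 8.55%, although such regions account for part of the excess. Unspecific recovery of open promoter chromatin stays open: 97.3% of the H3K4me3 peaks in the highest score decile overlapped DLX3 against 44.3% of those in the lowest, which both this explanation and binding of DLX3 at active promoters would give, and no list from a control antibody was used here. No biological explanation was tested.

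Few DLX3 peaks were called on chromosome X. Missing or unmappable sequence that reduced both lists alike is argued against as the whole cause. The ratio on X was 1.16 DLX3 peaks per H3K4me3 peak (interval 1.04 to 1.29), under the lowest autosome at 2.42. Sequence loss that falls more on DLX3 peaks off the mark than on H3K4me3 peaks was not tested and stays open. Fewer marked promoters as the whole cause is argued against by the density ratio of X to autosomes of 0.128 for DLX3 peaks off the mark, under the 0.447 of H3K4me3 peaks. A candidate explanation is a lower dose of X DNA, as in male tissue: the upper quartile of H3K4me3 scores was 1357 on X (bootstrap interval 1227 to 1497), under the lowest autosome at 1656, and 4.22% of the H3K4me3 peaks on X scored 3100 or more against 8.86 to 14.01% on the autosomes. The median H3K4me3 score on X, 578.0, was however not low. The upper quartile of DLX3 scores on X, 160.1, lay within the range of the autosomes (148.2 to 171.2). That comparison is not like for like. Of the DLX3 peaks, 48.5% on X lay on the mark, against 20.9 to 30.1% on the autosomes. Over all chromosomes the upper quartile was 253.3 on the mark and 132.6 off it. The DLX3 quartile on X therefore does not count against a lower dose. Weaker promoters on X or less DLX3 binding there stay open and untested.

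Broad signal split into neighbouring calls is argued against as the whole cause of the clusters of DLX3 peaks, for calls up to 1 kb apart. After joining peaks within 200 bp, 34.1% of the 64569 joined regions lay in dense windows, and after joining those within 1 kb, 22.0% of 57390 did, against 0.360% and 0.142% of such regions placed at random; before joining, 40.0% of the 69263 peaks did. Splitting over wider gaps was not tested and stays open, and in the densest windows on chromosomes 9 and 4 DLX3 peaks covered 77.1 and 72.5 kb of 100 kb. Empty stretches do not account for the clusters, since leaving out the 20 stretches over 5 Mb raised the random share only to 0.658%. Random placement ignores gene density, so clustering with genes was not tested.

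The longest stretch without a peak of either list was 65.5 Mb, on chromosome 4 (67788008 to 133267970). Whether its sequence is missing from rn5 was not tested, and the stretch is counted in the length used for the density of chromosome 4.

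The hypothesis that DLX3 peaks sit in the gap between paired H3K4me3 peaks was not borne out. Of 2070 gaps of 200 to 2000 bp, 3.04% held a DLX3 peak centre (Wilson interval 2.39 to 3.88%), against 3.82% of 3663 flanking stretches of the same length that were free of the mark (3.25 to 4.49%).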
